A study of Homo sapiens with 32 samples.

How the data were processed

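RNA had been sequenced from 32 libraries of 14 glioblastoma specimens, in 5 groups that the labels give: A2B5plus (n = 7), endothelial (n = 11), unsorted tumor (n = 8), gray matter (n = 3) and white matter (n = 3). Per the labels, total RNA was extracted with Trizol, amplified with a low-input NuGEN Ovation kit and made into libraries with TruSeq Nano. The deposited table holds 1 FPKM value per gene and library, made by the authors from reads per gene divided by gene length and library total. Their processing notes name CASAVA 1.8.2 and build hg38. The aligner, the counting tool, the gene annotation, its strand setting and any filter are not given in the sources used here. Raw reads were not used here.

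The table had 26282 gene rows and 32 sample columns, each matched to a sample by its description field. Whole reads were recovered from the FPKM values, since the values of a gene stand in ratios of whole numbers. In 24552 genes with a value above 0, 100% of 578979 values were whole reads within 0.01 of a read, and the recovery was tested on 2000 simulated genes, of which 100% came back exactly. Reads in genes ranged from 1634651 to 10381069 per library, which limits the precision of low values and covers counting error alone. Of 28 symbols that had become dates, 26 were repaired through their Entrez identifiers. The 108 Y-linked, XIST and TSIX rows were left out because they can identify a person, which left 26174. No mitochondrially encoded gene was in the table. The GC content of transcripts and gene positions came from GENCODE 29.

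The 6 comparisons were fixed before the data were examined, as were 35 gene lists with 750 members (736 found, 2 of them by an older symbol), the sort check genes and the rule for naming genes. Each was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), the pseudocount being 1, with a mean-variance trend, for genes with 1 FPKM or more in at least 3 samples of the fit. The tumor groups shared one fit, and unsorted tumor, gray matter and white matter another. All p values are Benjamini-Hochberg adjusted over the genes tested, with a threshold of 0.05, two-sided. Lists with at least 5 tested members were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01. The median of a list is that of its members' log2 differences, and its adjusted p is that of camera over the lists of a comparison. Members of a list not counted as rising or falling did not pass. Beside it stand camera with an estimated correlation and fry. Erythrocyte markers had too few tested members, and the mitochondrial list none.

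The rule named in each comparison the 6 largest rises and the 6 largest falls among genes that passed, had a mean of 5 FPKM or more in the higher group and changed the same way in every specimen with both groups, or whose ranges did not overlap where no specimen had both. It also named up to 3 members of each list with the smallest adjusted p, and the sort check genes PECAM1, VWF, CDH5, CLDN5, SOX2, OLIG2, PDGFRA, GFAP and PTPRC. Not every gene it names is given. It left out 4742 rows of small or ribosomal RNA, pseudogenes or no symbol.

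Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean of 5 FPKM or more, values rescaled to a common sum, quantile normalization, upper quartile scaling, the 2 groups fitted alone, 1 fit of all 5 groups, the specimen as a replicate block or as a random effect, array weights, no trend, robust eBayes, number-coded specimens alone, the kind of code as a covariate, each library left out in turn, and an exact permutation test of the sort check genes, adjusted over these in all comparisons, which 3 against 3 libraries cannot pass. Chosen after seeing the data were limma-voom on the recovered reads, leaving out 6 libraries with fewer than 16000 genes detected (5 A2B5plus, 1 endothelial), taking off the GC trend of each library over 20 bins, and that together with the block. The specimen, not in the main model, left a correlation within specimens of 0.104 among tumor libraries and 0.503 in unsorted tissue.

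In reads simulated with the spread of each gene, 0.12% or fewer of unchanged genes were called. Of genes changed 4-fold, 36% to 64% were recovered. With a simulated GC trend 44.3% of unchanged genes were called, or 0.173% after its removal, so the 0.12% does not cover such trends. Random lists (10000) were matched on gene length, GC content or both and on level, among the 100 nearest genes, and a check on 40 simulated lists put 92.5% of unmoved lists inside and 100% of moved ones above. Permutation tests of relations used 100000 resamples, or all orders with fewer than 10 samples. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.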

Results

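RNA sequencing had measured gene expression, as FPKM (fragments per kilobase of gene, scaled to the reads of each library), in 32 libraries of total RNA from 14 specimens, all labelled glioblastoma (GBM), the most aggressive primary brain tumor of adults. Dissociated tumor had been sorted by FACS, flow cytometry of labelled cells, into A2B5plus and endothelial cells. Of 11 tumor specimens, 11 gave an endothelial library, 7 an A2B5plus library and 8 a library of unsorted tumor. A2B5 is an antibody against gangliosides of glial progenitor and many glioma cells. The other 3 specimens gave 1 unsorted gray matter and 1 unsorted white matter library each, and the labels do not say whether these held tumor. The code of 1 of these 3 resembles that of a tumor specimen, and the 2 were treated as different because the labels do not link them. The markers of the endothelial gate are not given in the sources used here. Libraries are named by group and specimen number (1 to 14).

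Reads in genes, recovered from the FPKM values, ranged over 1634651 to 10381069 in the A2B5plus, 2266162 to 10230222 in the endothelial, 3981370 to 7064434 in the unsorted tumor, 5944908 to 7503443 in the gray matter and 3532037 to 9184691 in the white matter libraries. Fewer than 16000 genes had a read in 6 gene-poor libraries, of which 5 were A2B5plus and 1 was endothelial. Levels fell with the GC content of transcripts more steeply in unsorted than in sorted libraries. Spearman's rho of level against GC content, across 10428 genes that are not independent replicates, was -0.545 to -0.411 in unsorted tumor, -0.470 to -0.400 in gray matter and -0.487 to -0.239 in white matter. It was -0.202 to 0.0355 in the endothelial and -0.111 to 0.0584 in the A2B5plus libraries.

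**Figure D1:**
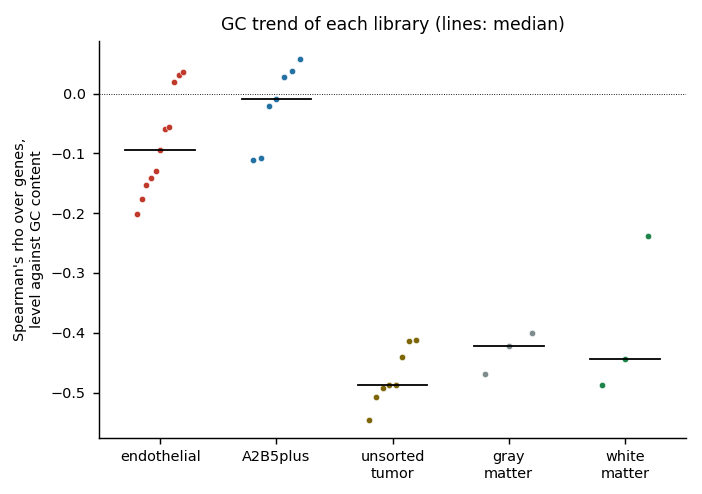
Spearman's rho of gene level against transcript GC content in each of the 32 libraries, by group, with lines at the group medians. Endothelial and A2B5plus libraries lay between -0.202 and 0.0584, and unsorted tumor libraries between -0.545 and -0.411.

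The first comparison set endothelial against A2B5plus libraries. The former were rich in endothelial and myeloid transcripts, the latter in those of myelin and of glioma cells or normal glia, not told apart. PECAM1 (chromosome 17, 64319415 to 64413776 on GRCh38), an adhesion molecule of endothelial cells that leukocytes also carry, stood at 66.6 ± 24.3 FPKM (SD, n = 11) in the endothelial and at 4.08 ± 8.94 FPKM (SD, n = 7) in the A2B5plus libraries, a difference of 4.78 ± 0.45 in log2(FPKM + 1) (SE, adjusted p = 5.9e-09). The leukocyte antigen gene PTPRC stood at 182 ± 81.8 against 26.4 ± 31.8 FPKM (3.88 ± 0.62, adjusted p = 1.7e-05). SOX2 and OLIG2, transcription factors of glioma stem-like and oligodendrocyte lineage cells, fell to 0.614 ± 0.679 and 0.217 ± 0.234 FPKM from 42.5 ± 40.3 and 29.8 ± 22.0 FPKM (-4.43 ± 0.38 and -4.29 ± 0.36, adjusted p = 1.3e-09 and 4.6e-10). These 4 genes moved the same way in 7 of 7 specimens with both libraries.

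Beside PECAM1, the named genes with the largest rises were the lysozyme gene LYZ (4.84 ± 0.77, adjusted p = 2.0e-05), the pattern receptor gene TLR2 (4.77 ± 0.60, adjusted p = 7.0e-07), the endothelial transcription factor gene ERG (4.68 ± 0.61, adjusted p = 1.0e-06), the complement gene C3 (4.63 ± 0.49, adjusted p = 4.4e-08) and KLHL6-AS1 (4.63 ± 0.53, adjusted p = 1.4e-07). Among the largest falls were those of the myelin gene MOBP (-5.89 ± 1.07, adjusted p = 9.6e-05), of SOX2-OT (-6.83 ± 0.46, adjusted p = 1.2e-11), of the transferrin gene TF (-6.13 ± 0.74, adjusted p = 3.5e-07), of the metallothionein gene MT3 (-6.12 ± 0.63, adjusted p = 2.4e-08) and of the tubulin gene TUBB4A (-5.87 ± 0.69, adjusted p = 2.4e-07), all in 7 of 7 specimens. KLHL6-AS1 lies antisense to KLHL6, and SOX2 (chromosome 3, 181711924 to 181714436) within SOX2-OT (180989762 to 181836880) on the same strand, so the reads of these overlapping genes cannot be told apart where the counting did not separate them. LYZ passed under 45 of 46 alternatives (adjusted p = 1.3e-07 to 0.152), but not without the 6 gene-poor libraries (2.65), as did MOBP (adjusted p = 3.5e-06 to 0.144, -3.92 there).

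**Figure D2:**
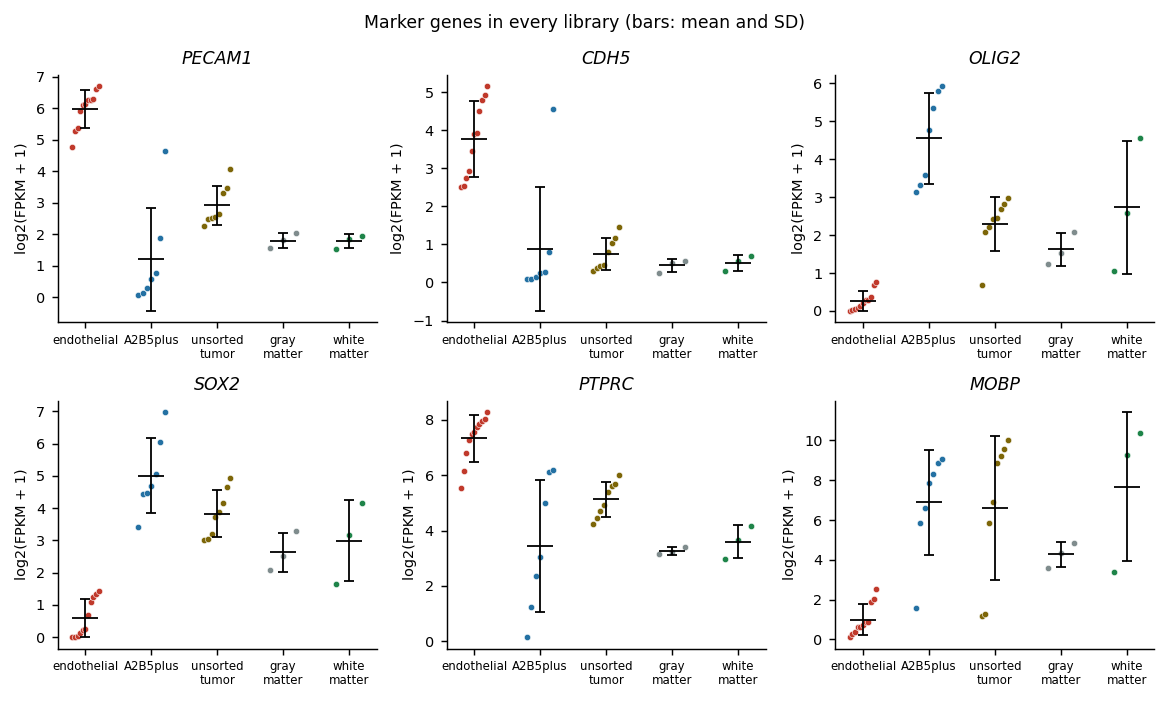
Levels of 6 marker genes in every library, as log2(FPKM + 1), with bars at the group mean and SD. PECAM1, CDH5 and PTPRC were highest on average in the endothelial libraries, and SOX2, OLIG2 and MOBP were lower there than in the A2B5plus libraries.

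The vascular lists rose. Of 19 pan-endothelial markers, 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.95, adjusted p = 5.0e-10, or 0.148 with an estimated correlation). VWF, a clotting factor carrier, rose by 3.46 ± 0.52, and the junction gene CDH5 by 2.88 ± 0.49 (adjusted p = 8.5e-06 and 4.6e-05). The tight junction gene CLDN5 rose by 1.49 ± 0.56 (adjusted p = 0.0431). It passed under 28 of 46 alternatives (adjusted p = 0.00262 to 0.214), but not without A2B5plus 1, 2, 3, 7 or 10, or endothelial 5, 6, 7, 9, 10 or 11 (1.23 to 1.52), with array weights (1.25), the 2 groups fitted alone (1.49), no filter (1.49), an exact permutation test (1.49) and quantile normalization (1.27), within the number-coded specimens (1.08) and without the 6 gene-poor libraries (2.30). Of 25 blood-brain barrier genes of endothelium, 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.44, adjusted p = 9.0e-05, or 0.399 with an estimated correlation). Of 24 tip cell and tumour endothelium genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.32, adjusted p = 7.1e-07, or 0.105 with an estimated correlation). DLL4 (1.76 ± 0.22, adjusted p = 3.7e-07), a NOTCH ligand of arteries and sprouts, and PLVAP (2.63 ± 0.37, adjusted p = 3.5e-06), of fenestrated vessels, were among these. Of 15 arterial endothelium genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.02, adjusted p = 4.7e-04, or 0.321 with an estimated correlation). Of 12 venous and activated endothelium genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 1.03, adjusted p = 0.00851, or 0.148 with an estimated correlation). Of 20 vascular basement membrane genes, 15 rose and 0 fell (15 and 0 adjusted over the list alone, median 1.49, adjusted p = 1.5e-06, or 0.148 with an estimated correlation). Of 17 pericyte and smooth muscle markers, 9 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.16, adjusted p = 0.00233, or 0.451 with an estimated correlation). PDGFRB (2.13 ± 0.41, adjusted p = 2.1e-04), a growth factor receptor of pericytes, and the smooth muscle actin gene ACTA2 (3.11 ± 0.65, adjusted p = 4.5e-04) rose. The list did not pass at a mean of 5 FPKM or more (1.25), alone of 46 alternatives (adjusted p = 2.9e-06 to 0.061). Of 21 TGF-beta and BMP pathway genes, 11 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.93, adjusted p = 2.6e-04, or 0.105 with an estimated correlation). In A2B5plus 6, PECAM1 stood at 24.3 and VWF at 32.3 FPKM, against at most 2.72 and 0.721 in the others.

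Leukocyte lists other than that of T and NK cells rose as well. Of 25 microglia and macrophage markers, 24 rose and 0 fell (24 and 0 adjusted over the list alone, median 3.01, adjusted p = 1.3e-13, or 0.105 with an estimated correlation). Of 10 neutrophil markers, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 2.04, adjusted p = 5.0e-07, or 0.105 with an estimated correlation). Of 18 MHC class I and II genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone, median 1.91, adjusted p = 8.0e-08, or 0.105 with an estimated correlation). Of 25 interferon response genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.04, adjusted p = 0.00851, or 0.451 with an estimated correlation). This list passed under 44 of 46 alternatives (adjusted p = 8.0e-06 to 0.162), but not at a mean of 5 FPKM or more (1.35) and within the number-coded specimens (0.61). Of 25 dissociation and immediate early genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.95, adjusted p = 0.00337, or 0.451 with an estimated correlation). This list passed under 45 of 46 alternatives (adjusted p = 1.7e-04 to 0.0587), but not with limma-voom (0.78), and its median was 0.57 without A2B5plus 10. Of 6 T and NK cell markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.74, adjusted p = 0.16). This list passed without A2B5plus 9 (1.02) and with array weights (1.03) (adjusted p = 0.00605 to 0.856 over its 44 alternatives). Over the 11 endothelial libraries, the mean of the macrophage list fell as that of the pan-endothelial list rose (Pearson's r = -0.741, permutation p = 0.00938, adjusted p = 0.0202 over 5 relations, and Spearman's rho = -0.754, permutation p = 0.0102, both two-sided). Without the 2 libraries farthest from the median, r was -0.846 and rho -0.767 (exact permutation p = 0.00193 and 0.0214). Within the 8 number-coded libraries they were -0.544 and -0.667 (exact permutation p = 0.164 and 0.0831), so the relation did not pass there, and the 3 others were too few for a value.

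**Figure D3:**
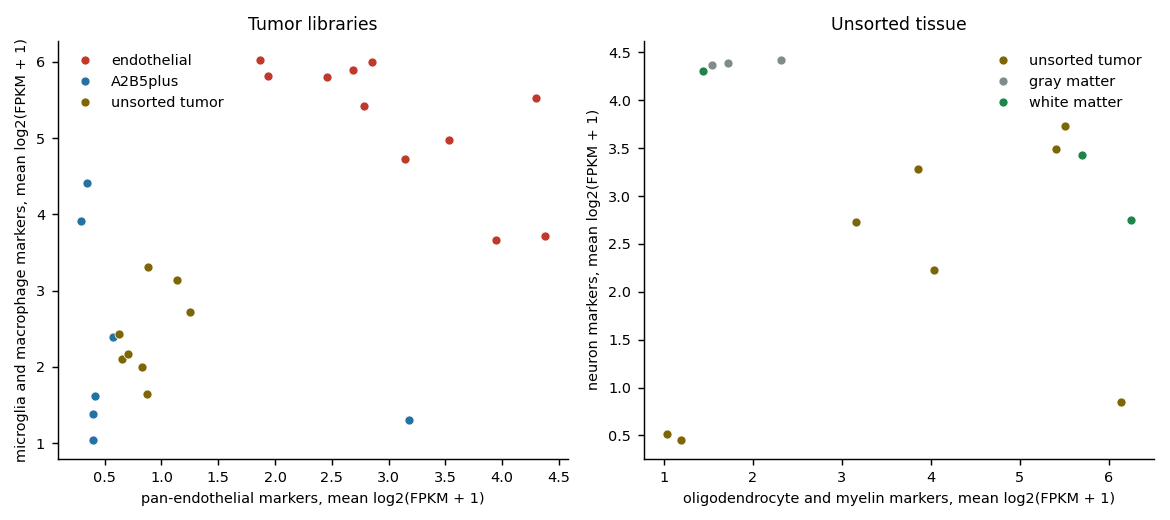
Mean log2(FPKM + 1) of the macrophage list against that of the pan-endothelial list in the tumor libraries (left), and of the neuron list against the myelin list in unsorted tissue (right), 1 point per library. Endothelial libraries spanned pan-endothelial means from 1.87 to 4.38, and white matter libraries myelin means from 1.44 to 6.25.

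Glioma lists other than the mesenchymal-like one, and glial and neuronal lists, fell in the endothelial relative to the A2B5plus libraries. Of 24 oligodendrocyte progenitor-like glioma genes, 0 rose and 21 fell (0 and 21 adjusted over the list alone, median -2.89, adjusted p = 1.1e-18, adjusted p = 0.00142 with an estimated correlation as well). Of 20 neural progenitor-like glioma genes, 1 rose and 12 fell (1 and 14 adjusted over the list alone, median -1.33, adjusted p = 1.6e-07, or 0.105 with an estimated correlation). Of 22 astrocyte-like glioma genes, 0 rose and 15 fell (0 and 17 adjusted over the list alone, median -2.05, adjusted p = 1.4e-11, or 0.105 with an estimated correlation). S100B (-4.76 ± 0.43, adjusted p = 3.5e-09) and GFAP (-3.30 ± 0.54, adjusted p = 3.0e-05), the intermediate filament of astrocytes, fell. Of 18 glioma stem cell genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone, median -0.57, adjusted p = 1.1e-05, or 0.105 with an estimated correlation). Of 16 growth factor receptor and cell cycle kinase genes of glioma, 1 rose and 7 fell (1 and 8 adjusted over the list alone, median -0.80, adjusted p = 0.00216, or 0.106 with an estimated correlation). Of 20 oligodendrocyte and myelin markers, 0 rose and 20 fell (0 and 20 adjusted over the list alone, median -4.08, adjusted p = 1.1e-16, or 0.105 with an estimated correlation). Of 18 astrocyte markers of normal brain, 0 rose and 12 fell (1 and 12 adjusted over the list alone, median -1.43, adjusted p = 1.6e-07, or 0.106 with an estimated correlation). Of 21 neuron markers, 0 rose and 5 fell (0 and 3 adjusted over the list alone, median -0.98, adjusted p = 0.00159, or 0.451 with an estimated correlation). Of 22 synapse genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone, median -0.73, adjusted p = 1.0e-05, or 0.25 with an estimated correlation). The normal astrocyte list passed under 45 of 46 alternatives (adjusted p = 6.5e-09 to 0.271), but not without the 6 gene-poor libraries (-0.49). The neuron list passed under 44 of 46 alternatives (adjusted p = 9.0e-05 to 0.411), but not with array weights (-0.92) and without the 6 gene-poor libraries (-0.49), and its median was -0.63 without A2B5plus 10.

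Ribosomal protein genes differed little. Of 46 cytosolic ribosomal protein genes, 1 rose and 8 fell (1 and 6 adjusted over the list alone, median -0.31, adjusted p = 0.01, or 0.688 with an estimated correlation). The list passed under 41 of 46 alternatives (adjusted p = 5.4e-05 to 0.358), but not without A2B5plus 7 or 10 (-0.42 to -0.21), with quantile normalization (-0.25) and upper quartile scaling (0.13) and without the 6 gene-poor libraries (-0.06), with the sign turned by upper quartile scaling, and the median was -0.54 without endothelial 9. Of 24 housekeeping genes, 1 rose and 3 fell (0 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.423). Their mean (-0.10) and test direction were negative. Of 24 hypoxia genes, 6 rose and 5 fell (8 and 5 adjusted over the list alone, median 0.55, adjusted p = 0.74). Of 14 fibroblast and collagen matrix genes, 7 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.61, adjusted p = 0.145). Of 25 mesenchymal-like glioma genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.57, adjusted p = 0.215). Of 21 angiogenic ligands, 8 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.40, adjusted p = 0.184). PDGFB (2.90 ± 0.28, adjusted p = 7.8e-09), a growth factor for pericytes, rose. Of 17 NOTCH pathway genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.506). Of 16 WNT pathway targets and regulators, 5 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.972). Of 11 ganglioside synthesis genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone, median -0.31, adjusted p = 0.798). Of 25 cell cycle genes, 2 rose and 1 fell (0 and 0 adjusted over the list alone, median 0.21, adjusted p = 0.705). Erythrocyte markers had too few members measured for a test, with a mean log2(FPKM + 1) of 0.51 ± 0.14 (SD, n = 11) in the endothelial and 0.31 ± 0.35 (SD, n = 7) in the A2B5plus libraries, and no member of the mitochondrial list was in the table.

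With limma, 2758 genes rose and 1820 fell of 14496 tested, 1884 and 1273 of them by 2-fold or more. The share of rises was 60.2%, and 75.5% with upper quartile scaling and 50.1% with quantile normalization. The median difference of all genes was 0.08, and 0.39 and 0.30 with values rescaled to a common sum and with upper quartile scaling. The balance turned without the 6 gene-poor libraries, where 1158 genes rose and 1758 fell (39.7% rises), and with array weights, where 1797 rose and 2247 fell (44.4%). The former setting kept A2B5plus 1 and 2 alone in their group.

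The second comparison asked what the endothelial sort enriched or depleted relative to unsorted tumor. Of the named genes, inflammatory and immediate early genes rose most. The cytokine gene IL1B stood at 448 ± 341 FPKM (SD, n = 11) against 2.29 ± 3.10 FPKM (SD, n = 8), a difference of 6.81 ± 0.85 (SE, adjusted p = 4.1e-07). The chemokine gene CXCL8 stood at 499 ± 539 against 4.66 ± 9.15 FPKM (6.53 ± 0.86, adjusted p = 9.9e-07). The immediate early genes FOSB (6.80 ± 0.44, adjusted p = 4.0e-12), FOS (5.61 ± 0.52, adjusted p = 2.9e-09), DUSP1 (5.56 ± 0.51, adjusted p = 2.9e-09) and ZFP36 (5.36 ± 0.55, adjusted p = 2.0e-08), which respond fast to stress and growth signals, rose too. Among the largest falls were those of CDR1 (-7.65 ± 1.07, adjusted p = 2.3e-06), SOX2-OT (-6.58 ± 0.44, adjusted p = 9.9e-12), the lipid carrier gene PMP2 (-6.26 ± 0.51, adjusted p = 3.6e-10), PCDH9-AS3 (-5.84 ± 0.51, adjusted p = 1.1e-09) and the myelin gene MOBP (-5.61 ± 1.02, adjusted p = 6.7e-05). Each of these 11 genes moved the same way in 8 of 8 specimens with both libraries. CDR1 lies antisense within LINC00632, and PCDH9-AS3 antisense within PCDH9, so their reads cannot be told with certainty from those of the other strand.

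Vascular genes rose. Of 19 pan-endothelial markers, 19 rose and 0 fell (19 and 0 adjusted over the list alone, median 2.27, adjusted p = 5.2e-08, or 0.238 with an estimated correlation). PECAM1 rose by 3.06 ± 0.44, VWF by 3.66 ± 0.50, CDH5 by 3.01 ± 0.47 and CLDN5 by 2.35 ± 0.54 (adjusted p = 2.8e-06, 1.7e-06, 1.0e-05 and 8.2e-04). Of 25 blood-brain barrier genes of endothelium, 20 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.76, adjusted p = 2.6e-05, or 0.28 with an estimated correlation). Of 24 tip cell and tumour endothelium genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone, median 1.65, adjusted p = 7.9e-06, or 0.238 with an estimated correlation). Of 15 arterial endothelium genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 0.92, adjusted p = 0.00141, or 0.28 with an estimated correlation). Of 12 venous and activated endothelium genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.29, adjusted p = 0.00675, or 0.238 with an estimated correlation). The arterial list passed under 44 of 45 alternatives (adjusted p = 1.6e-04 to 0.0536), but not with array weights (0.65), as did the venous list (adjusted p = 0.00251 to 0.0536, 1.12 there). A leukocyte source of the venous rise, here or above, was not tested. Of 20 vascular basement membrane genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.37, adjusted p = 2.7e-05, or 0.238 with an estimated correlation). Of 17 pericyte and smooth muscle markers, 15 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.77, adjusted p = 1.0e-04, or 0.279 with an estimated correlation). Of 21 TGF-beta and BMP pathway genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 1.06, adjusted p = 0.00225, or 0.238 with an estimated correlation). Of 17 NOTCH pathway genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.73, adjusted p = 0.00738, or 0.279 with an estimated correlation). The NOTCH list passed under 43 of 46 alternatives (adjusted p = 0.00290 to 0.259), but not with the GC trend taken off (0.42, or 0.56 with the block) and at a mean of 5 FPKM or more (0.64).

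Leukocyte and stress genes rose beside them. Of 25 microglia and macrophage markers, 24 rose and 0 fell (25 and 0 adjusted over the list alone, median 2.57, adjusted p = 1.6e-09, or 0.238 with an estimated correlation). PTPRC rose by 2.21 ± 0.59 (adjusted p = 0.00311). Of 10 neutrophil markers, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.8, adjusted p = 5.4e-05, or 0.238 with an estimated correlation). Of 18 MHC class I and II genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 2.49, adjusted p = 3.1e-10, or 0.217 with an estimated correlation). Of 25 interferon response genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.32, adjusted p = 0.00113, or 0.28 with an estimated correlation). Of 6 T and NK cell markers, 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 1.06, adjusted p = 0.0426, or 0.329 with an estimated correlation). The list passed under 37 of 44 alternatives (adjusted p = 0.00828 to 0.0869), but not without A2B5plus 7, or endothelial 8 or 9, or unsorted tumor 1 (0.91 to 1.11), with the kind of code as a covariate (1.20) and no filter (0.26) and without the 6 gene-poor libraries (1.39). Of 25 dissociation and immediate early genes, 24 rose and 0 fell (24 and 0 adjusted over the list alone, median 3.85, adjusted p = 2.4e-16, or 0.217 with an estimated correlation). Of 46 cytosolic ribosomal protein genes, 39 rose and 0 fell (42 and 0 adjusted over the list alone, median 1.72, adjusted p = 9.4e-11, or 0.238 with an estimated correlation). Of 24 housekeeping genes, 14 rose and 1 fell (14 and 2 adjusted over the list alone, median 0.93, adjusted p = 0.00796, or 0.238 with an estimated correlation). Of 25 mesenchymal-like glioma genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone, median 1.26, adjusted p = 0.00796, or 0.383 with an estimated correlation). Of 24 hypoxia genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.58, adjusted p = 0.158). The hypoxia list passed without unsorted tumor 8 (0.86) and with the replicate block (0.74, or 0.85 with the GC trend taken off) (adjusted p = 0.0278 to 0.284 over its 46 alternatives).

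Glioma lists other than the mesenchymal-like one, and glial and neuronal lists, fell. Of 24 oligodendrocyte progenitor-like glioma genes, 2 rose and 13 fell (2 and 13 adjusted over the list alone, median -1.18, adjusted p = 7.3e-05, or 0.238 with an estimated correlation). Of 20 neural progenitor-like glioma genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.74, adjusted p = 1.3e-04, or 0.238 with an estimated correlation). Of 22 astrocyte-like glioma genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone, median -0.76, adjusted p = 2.6e-05, or 0.238 with an estimated correlation). Of 18 glioma stem cell genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone, median -0.30, adjusted p = 0.0115, or 0.28 with an estimated correlation). Of 16 growth factor receptor and cell cycle kinase genes of glioma, 2 rose and 6 fell (2 and 6 adjusted over the list alone, median -0.71, adjusted p = 0.0215, or 0.238 with an estimated correlation). Of 20 oligodendrocyte and myelin markers, 0 rose and 17 fell (0 and 17 adjusted over the list alone, median -3.00, adjusted p = 6.5e-08, or 0.238 with an estimated correlation). Of 21 neuron markers, 0 rose and 17 fell (0 and 19 adjusted over the list alone, median -2.15, adjusted p = 2.5e-07, or 0.238 with an estimated correlation). Of 18 astrocyte markers of normal brain, 1 rose and 6 fell (1 and 6 adjusted over the list alone, median -0.55, adjusted p = 0.00610, or 0.329 with an estimated correlation). Of 22 synapse genes, 0 rose and 13 fell (0 and 13 adjusted over the list alone, median -0.90, adjusted p = 7.9e-06, or 0.238 with an estimated correlation). SOX2, OLIG2, PDGFRA and GFAP fell by 3.24 ± 0.37, 2.03 ± 0.34, 2.59 ± 0.45 and 2.27 ± 0.52 (adjusted p = 1.0e-07, 2.5e-05, 3.4e-05 and 8.2e-04). The fibroblast, angiogenic ligand, WNT, ganglioside and cell cycle lists did not pass (adjusted p = 0.243 to 0.65).

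In all, 4238 genes rose and 2922 fell of 14496 tested with limma. The share of rises was 59.2%, and 49.0% with quantile normalization, which moved the median of all genes from 0.19 to 0.03. Rescaling to a common sum and upper quartile scaling moved it to 0.05 and 0.07. Gene differences rose with GC content (Spearman's rho = 0.450 across 13458 genes, which are not independent replicates). With the GC trend of each library taken off, 3156 genes rose and 2012 fell, and 4023 calls were shared with the 7160 above. With array weights 6425 genes rose.

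**Figure D4:**
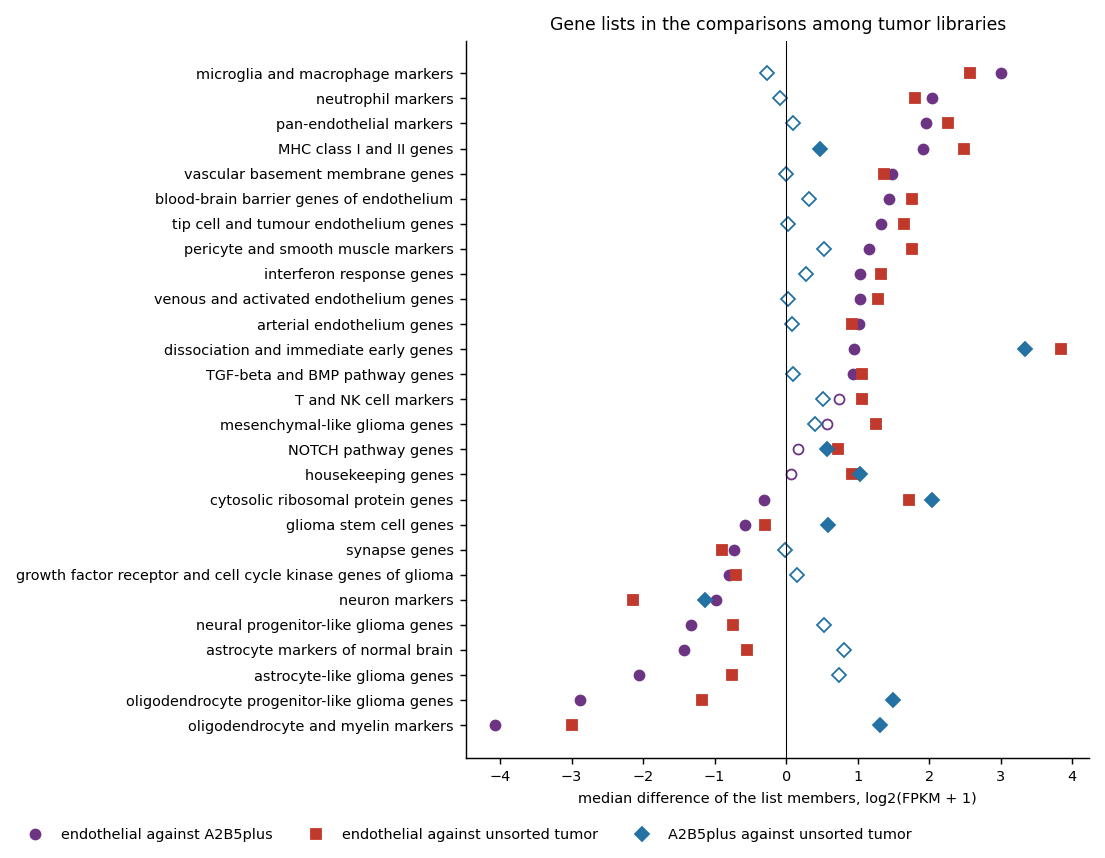
Median difference of the members of each list in log2(FPKM + 1), for lists past an adjusted p of 0.05 in at least 1 of the 3 comparisons among tumor libraries. Filled symbols passed the camera test with the preset correlation, and open symbols did not. The immediate early list lay at 3.85 for endothelial and 3.35 for A2B5plus against unsorted tumor, and the ribosomal list at 1.72 and 2.04. Upper quartile scaling turned the ribosomal list of endothelial against A2B5plus from -0.31 to 0.13.

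The third comparison asked what the A2B5 sort enriched or depleted. With the preset correlation 8 lists were higher in A2B5plus libraries than in unsorted tumor and 1 lower. None passed with an estimated correlation, and 6 with fry, among them the progenitor-like and immediate early lists (higher). OLIG2 stood at 29.8 ± 22.0 FPKM (SD, n = 7) against 4.33 ± 1.93 FPKM (SD, n = 8), a difference of 2.27 ± 0.38 (SE, adjusted p = 8.5e-05). SOX8 (2.56 ± 0.26, adjusted p = 1.8e-07), OLIG1 (2.39 ± 0.35, adjusted p = 1.4e-05) and the matrix proteoglycan gene BCAN (2.66 ± 0.35, adjusted p = 3.8e-06) rose as well. The largest rises of named genes were those of FOSB (5.96 ± 0.49, adjusted p = 4.3e-09), FOS (5.10 ± 0.58, adjusted p = 6.7e-07), EGR1 (4.96 ± 0.53, adjusted p = 3.3e-07), JUNB (4.46 ± 0.42, adjusted p = 5.8e-08), PPDPF (4.54 ± 0.50, adjusted p = 5.2e-07) and the ribosomal protein gene FAU (4.51 ± 0.42, adjusted p = 5.8e-08). The largest falls were those of PCDH9-AS3 (-3.04 ± 0.57, adjusted p = 2.7e-04), UACA (-2.96 ± 0.46, adjusted p = 3.4e-05), SUMO4 (-2.88 ± 0.42, adjusted p = 1.4e-05), LINC00632 (-2.84 ± 0.52, adjusted p = 1.9e-04), the GABA receptor gene GABRB2 (-2.82 ± 0.56, adjusted p = 4.3e-04) and FAM220A (-2.80 ± 0.41, adjusted p = 1.5e-05). Each of these 12 moved the same way in 5 of 5 specimens with both libraries. SUMO4 lies within TAB2, and LINC00632 and PCDH9-AS3 share their loci with CDR1 and PCDH9.

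Of 24 oligodendrocyte progenitor-like glioma genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.50, adjusted p = 1.4e-07, or 0.138 with an estimated correlation). Of 25 dissociation and immediate early genes, 20 rose and 0 fell (23 and 0 adjusted over the list alone, median 3.35, adjusted p = 5.0e-16, or 0.138 with an estimated correlation). Of 46 cytosolic ribosomal protein genes, 38 rose and 0 fell (39 and 0 adjusted over the list alone, median 2.04, adjusted p = 3.3e-21, or 0.281 with an estimated correlation). Of 24 housekeeping genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone, median 1.03, adjusted p = 5.5e-04, or 0.28 with an estimated correlation). Of 18 glioma stem cell genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.59, adjusted p = 0.0325, or 0.968 with an estimated correlation). This median and those of NOTCH and MHC lay below the housekeeping one. The stem cell list passed under 34 of 46 alternatives (adjusted p = 0.00879 to 0.146), but not without A2B5plus 3 or 7, or unsorted tumor 5, 6 or 7 (0.44 to 0.56), with array weights (0.65), the 2 groups fitted alone (0.59), a pseudocount of 0.1 (0.68), quantile normalization (0.44) and values rescaled to a common sum (0.36), at a mean of 5 FPKM or more (1.18) and without the 6 gene-poor libraries (0.95). Of 20 oligodendrocyte and myelin markers, 9 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.32, adjusted p = 0.0112, or 0.968 with an estimated correlation). These myelin genes passed under 39 of 46 alternatives (adjusted p = 2.2e-05 to 0.78), but not without A2B5plus 7 or 9, or unsorted tumor 3 or 8 (0.85 to 1.11), with array weights (1.01), within the number-coded specimens (1.31) and without the 6 gene-poor libraries (0.72). Of 17 NOTCH pathway genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.57, adjusted p = 0.0325, or 0.968 with an estimated correlation). The NOTCH list passed under 35 of 46 alternatives (adjusted p = 0.00879 to 0.991), but not without A2B5plus 3 or 6, or unsorted tumor 6 or 7 (0.46 to 0.63), with the GC trend taken off (0.52), array weights (0.85), the kind of code as a covariate (0.57), the replicate block (0.56) and the replicate block and the GC trend taken off (0.43), at a mean of 5 FPKM or more (0.79) and without the 6 gene-poor libraries (0.62). Of 18 MHC class I and II genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.0325, or 0.968 with an estimated correlation). The MHC list passed under 38 of 46 alternatives (adjusted p = 0.00360 to 0.598), but not without A2B5plus 2 or 7, or unsorted tumor 6 or 7 (0.33 to 0.48), with the GC trend taken off (0.17), array weights (0.77) and the replicate block and the GC trend taken off (0.54) and without the 6 gene-poor libraries (1.05). Of 21 neuron markers, 1 rose and 6 fell (1 and 6 adjusted over the list alone, median -1.13, adjusted p = 0.0112, or 0.968 with an estimated correlation). The neuron list passed under 44 of 46 alternatives (adjusted p = 1.4e-08 to 0.399), but not without unsorted tumor 7 (-0.93) and at a mean of 5 FPKM or more (-1.15).

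Of the sort check genes, SOX2 rose by 1.18 ± 0.41 (adjusted p = 0.0294). It passed under 33 of 47 alternatives (adjusted p = 0.00754 to 0.319), but not without A2B5plus 3 or 7, or unsorted tumor 2, 5 or 6 (0.85 to 1.09), with the GC trend taken off (0.98), the 2 groups fitted alone (1.18), limma-voom (1.37), an exact permutation test (1.18), a pseudocount of 0.1 (1.24), quantile normalization (0.81), upper quartile scaling (0.52) and values rescaled to a common sum (0.91) and without the 6 gene-poor libraries (1.04). PECAM1 fell by 1.71 ± 0.49 (adjusted p = 0.00862), and it passed under 46 of 47 alternatives (adjusted p = 3.3e-05 to 0.0813), but not with the replicate block and the GC trend taken off (-1.40). VWF, CDH5, CLDN5, PDGFRA, GFAP and PTPRC did not pass (adjusted p = 0.821, 0.878, 0.287, 0.823, 0.18 and 0.0527). GFAP passed without A2B5plus 9 (1.62) and within the number-coded specimens (1.50) (adjusted p = 0.0131 to 0.796 over its 47 alternatives). PTPRC passed without A2B5plus 2, 7 or 9, or endothelial 11, or unsorted tumor 7 (-2.13 to -1.68), with 1 fit of all 5 groups (-1.68), a pseudocount of 0.1 (-2.15), a pseudocount of 0.5 (-1.87), quantile normalization (-2.02), the specimen as a random effect (-1.62), upper quartile scaling (-2.24) and values rescaled to a common sum (-2.47) and at a mean of 5 FPKM or more (-1.68) (adjusted p = 0.00963 to 0.627 over its 47 alternatives). Of 11 ganglioside synthesis genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone, median -0.30, adjusted p = 0.431). Of these genes, which make the antigens of A2B5, the ceramide glucosyltransferase gene UGCG (-1.95 ± 0.50, adjusted p = 0.00412) fell, and it passed under 43 of 46 alternatives (adjusted p = 6.9e-04 to 0.693), but not with array weights (-1.19) and the replicate block and the GC trend taken off (-0.78) and without the 6 gene-poor libraries (-0.38).

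Of 19 pan-endothelial markers, 1 rose and 2 fell (1 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.863). The mean (-0.08) and the test were negative. Without A2B5plus 6 the median was -0.41, and VWF, CDH5 and CLDN5 differed by -0.49, -0.48 and 0.33, all short of the threshold (adjusted p = 0.119, 0.344, 0.359 and 0.679). With a negative median, this list passed with the replicate block and the GC trend taken off (-0.46) and without the 6 gene-poor libraries (-0.45) (adjusted p = 0.0104 to 0.983 over its 46 alternatives). The mesenchymal-like list passed without unsorted tumor 8 (0.68), with the replicate block (0.76) and within the number-coded specimens (0.75) (adjusted p = 0.0151 to 0.683 over its 46 alternatives). The astrocyte-like list passed without A2B5plus 1, 2 or 9 (0.71 to 0.92) and with no filter (0.73) and values rescaled to a common sum (0.47) (adjusted p = 0.00999 to 0.664 over its 46 alternatives). The normal astrocyte list passed without A2B5plus 1, 2 or 9 (0.71 to 0.98) and with no filter (0.81) (adjusted p = 0.0132 to 0.832 over its 46 alternatives). The arterial list passed with the replicate block and the GC trend taken off (-0.43) (adjusted p = 0.021 to 0.937 over its 45 alternatives). The other vascular and the leukocyte lists did not pass (adjusted p = 0.209 to 0.981). Nor did the neural progenitor-like, receptor, hypoxia, angiogenic, TGF-beta, WNT, cell cycle, interferon and synapse lists (adjusted p = 0.329 to 0.938).

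With limma, 2419 genes rose and 2041 fell of 14496. The share of rises was 54.2%, and 34.2% with values rescaled to a common sum and 28.9% with upper quartile scaling, which moved the median of all genes from 0.01 to -0.49 and -0.30. Gene differences rose with GC content (Spearman's rho = 0.636 across 13458 genes). With the GC trend of each library taken off 1096 genes rose and 779 fell, of which 1284 were among the 4460 above. Without the 6 gene-poor libraries 3421 genes rose and 712 fell (82.8% rises), with array weights 71.8% were rises, and with the 2 groups fitted alone 1304 genes fell.

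The fourth comparison set gray against white matter of the same 3 specimens. With the preset correlation 5 lists passed, but with fry or an estimated correlation 0 did, and no single gene passed. The median difference, gray minus white, was negative for 20 myelin genes (-2.56, adjusted p = 6.4e-15, adjusted p = 0.985 with an estimated correlation). It was positive for 23 synapse genes (0.72, adjusted p = 1.1e-07, adjusted p = 0.985 with an estimated correlation) and for 21 neuron genes (0.95, adjusted p = 7.4e-05, adjusted p = 0.985 with an estimated correlation). It was negative for the oligodendrocyte progenitor-like list (-0.46, adjusted p = 0.00249, adjusted p = 0.985 with an estimated correlation) and for ribosomal protein genes (-0.41, adjusted p = 4.6e-05, adjusted p = 0.985 with an estimated correlation). In each of these 5 lists 0 members passed, over all genes and adjusted over the list alone. The myelin gene CNP stood at 2.56 ± 0.768 FPKM (SD, n = 3) in gray and at 43.0 ± 40.3 FPKM (SD, n = 3) in white matter (-2.52 ± 1.25, adjusted p = 0.988). The vesicle gene SYP stood at 5.31 ± 1.83 against 2.32 ± 0.720 FPKM (0.91 ± 0.43, adjusted p = 0.988). PECAM1, SOX2, OLIG2, PDGFRA, GFAP and PTPRC did not pass (adjusted p = 1, 0.993, 0.988, 1, 0.988 and 0.989).

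White matter 14 differed from the other white matter libraries. The mean log2(FPKM + 1) of its myelin list was 1.44, against 5.70 in white matter 12 and 6.25 in white matter 13, and between 1.55 and 2.32 in gray matter. Without it the medians were -4.06 for myelin, 1.52 for neuron, -0.94 for progenitor-like and -0.91 for ribosomal genes. Without white matter 13, whose myelin genes were highest, they were 0.45 for synapse genes, 0.49 for neuron genes and -0.06 for progenitor-like genes, and the sign turned to 0.18 for ribosomal genes, the last 3 without a call (adjusted p = 6.6e-10 to 0.0966, adjusted p = 4.2e-05 to 0.0958 and adjusted p = 3.0e-09 to 0.33 over all alternatives). The ribosomal median was -0.23 without gray matter 14. The synapse and progenitor-like lists also lost their calls among genes with a mean of 5 FPKM or more (0.78 and -0.26). The interferon list passed with the 2 groups fitted alone (-0.49), the replicate block (-0.49) and the replicate block and the GC trend taken off (-0.49) (adjusted p = 0.00317 to 0.816 over its 30 alternatives). The other lists did not pass, and of the 31 tested, median, mean and test differed in sign in 10. Limma called 0 of 11009 genes, with 288 at an unadjusted p under 0.05, limma-voom also called 0, and without white matter 14 limma called 2 higher and 9 lower in gray matter.

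The fifth comparison set unsorted tumor against gray matter, from different specimens. With the preset correlation 11 lists were higher in the tumor and 4 lower. Of these 0 passed with an estimated correlation and 3 with fry, among them macrophage genes (higher) and synapse genes (lower). The secreted phosphoprotein gene SPP1 stood at 90.4 ± 65.2 FPKM (SD, n = 8) against 2.57 ± 0.639 FPKM (SD, n = 3), a difference of 4.34 ± 0.73 (SE, adjusted p = 0.00434). S100A11 (3.15 ± 0.55, adjusted p = 0.00518) and the Fc receptor gene FCGR2A (3.07 ± 0.44, adjusted p = 0.00277) rose, as did CHI3L1 (4.04 ± 1.23, adjusted p = 0.0422), a secreted glycoprotein of glioma and inflammation, the chaperone gene CRYAB (3.16 ± 0.87, adjusted p = 0.028), which overlaps HSPB2, and GLDN (3.13 ± 0.86, adjusted p = 0.028). The largest falls of named genes were those of the guanine deaminase gene GDA (-3.88 ± 1.04, adjusted p = 0.025), the channel subunit genes SCN3B (-3.76 ± 1.0, adjusted p = 0.0242) and KCNV1 (-3.61 ± 0.85, adjusted p = 0.0144), HMP19 (-3.56 ± 0.61, adjusted p = 0.00498), the neuronal transcription factor gene MYT1L (-3.56 ± 1.05, adjusted p = 0.0373) and the vesicle gene RAB3C (-3.44 ± 0.79, adjusted p = 0.013). Group ranges did not overlap for these 12 genes, which the naming rule required.

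Of 21 microglia and macrophage markers, 11 rose and 0 fell (16 and 0 adjusted over the list alone, median 1.43, adjusted p = 5.3e-10, or 0.659 with an estimated correlation). FCGR3A (2.91 ± 0.42, adjusted p = 0.00280) and LAPTM5 (2.76 ± 0.43, adjusted p = 0.00337) were among these. Of 11 MHC class I and II genes, 6 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.30, adjusted p = 4.5e-06, or 0.659 with an estimated correlation). Of 20 interferon response genes, 2 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.99, adjusted p = 3.0e-05, or 0.659 with an estimated correlation). Of 21 mesenchymal-like glioma genes, 4 rose and 0 fell (10 and 0 adjusted over the list alone, median 1.50, adjusted p = 1.3e-05, or 0.659 with an estimated correlation). Of 21 cell cycle genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 1.18, adjusted p = 4.1e-05, or 0.659 with an estimated correlation). Of 14 tip cell and tumour endothelium genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.98, adjusted p = 0.0117, or 0.659 with an estimated correlation). Of 12 vascular basement membrane genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.81, adjusted p = 0.00978, or 0.702 with an estimated correlation). Of 20 oligodendrocyte and myelin markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 1.81, adjusted p = 0.00104, or 0.739 with an estimated correlation). Of 42 cytosolic ribosomal protein genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.52, adjusted p = 4.9e-04, or 0.75 with an estimated correlation). Of 13 TGF-beta and BMP pathway genes, 1 rose and 0 fell (3 and 1 adjusted over the list alone, median 0.57, adjusted p = 0.0211, or 0.659 with an estimated correlation). Of 8 NOTCH pathway genes, 1 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.40, adjusted p = 0.0384, or 0.659 with an estimated correlation). The NOTCH list passed under 23 of 27 alternatives (adjusted p = 0.0211 to 0.104), but not without gray matter 13 (0.51) and with limma-voom (0.83), 1 fit of all 5 groups (0.15) and a pseudocount of 0.1 (0.79). The TGF-beta list passed under 25 of 28 alternatives (adjusted p = 0.00893 to 0.969), but not without unsorted tumor 2 (0.90), with 1 fit of all 5 groups (0.15) and at a mean of 5 FPKM or more (0.08), and its median was 0.86 without unsorted tumor 4. The basement membrane list passed under 27 of 28 alternatives (adjusted p = 0.00189 to 0.179), but not at a mean of 5 FPKM or more (0.80).

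Of 23 synapse genes, 0 rose and 18 fell (0 and 22 adjusted over the list alone, median -1.71, adjusted p = 8.6e-14, or 0.659 with an estimated correlation). Of 21 neuron markers, 0 rose and 10 fell (0 and 18 adjusted over the list alone, median -2.48, adjusted p = 9.4e-09, or 0.659 with an estimated correlation). Of 18 neural progenitor-like glioma genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone, median -0.88, adjusted p = 0.0117, or 0.659 with an estimated correlation). This list passed under 27 of 28 alternatives (adjusted p = 5.7e-04 to 0.179), but not at a mean of 5 FPKM or more (-1.19). Of 15 astrocyte markers of normal brain, 0 rose and 4 fell (0 and 5 adjusted over the list alone, median -0.54, adjusted p = 0.0158, or 0.659 with an estimated correlation). This list passed under 27 of 28 alternatives (adjusted p = 0.00447 to 0.137), but not at a mean of 5 FPKM or more (-0.54), and its median was -0.96 without gray matter 14. The other 16 lists tested did not pass, and 3 of these differed in sign between median, mean and test.

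Of the sort check genes, PECAM1 (1.12 ± 0.33, adjusted p = 0.0388) and PTPRC (1.87 ± 0.37, adjusted p = 0.00775) rose, and SOX2, OLIG2, PDGFRA, GFAP and CDH5 did not pass (adjusted p = 0.13, 0.453, 0.23, 0.198 and 0.403). GFAP passed with the 2 groups fitted alone (2.16) and an exact permutation test (2.16) (adjusted p = 0.0285 to 0.52 over its 29 alternatives). Limma called 474 genes higher and 1133 lower in the tumor, of 11009. Without gray matter 12, 13 or 14 these counts were 79 and 294, 55 and 184, and 61 and 310, and CRYAB, GLDN, GDA, SCN3B, KCNV1 and RAB3C lost their calls each time (values of -4.00 to 3.29, adjusted p = 2.3e-04 to 0.122 over all alternatives). CHI3L1 passed under 16 of 28 alternatives (adjusted p = 0.0213 to 0.161), but not without gray matter 12, 13 or 14, or unsorted tumor 1, 2, 3 or 4, or white matter 12 (3.76 to 4.13) and with the 2 groups fitted alone (4.04), limma-voom (5.63), no filter (4.04) and 1 fit of all 5 groups (4.04). MYT1L passed under 19 of 28 alternatives (adjusted p = 0.00767 to 0.135), but not without gray matter 12, 13 or 14, or unsorted tumor 4 or 5 (-3.62 to -3.34) and with limma-voom (-4.71), no filter (-3.56), a pseudocount of 0.1 (-4.34) and values rescaled to a common sum (-4.48). PECAM1 passed under 21 of 29 alternatives (adjusted p = 0.0224 to 0.407), but not without gray matter 12, 13 or 14, or unsorted tumor 4 or 8, or white matter 12 (1.0 to 1.23) and with no filter (1.12) and 1 fit of all 5 groups (1.12). PTPRC passed under 27 of 29 alternatives (adjusted p = 0.00435 to 0.244), but not without gray matter 13 (1.82) and with 1 fit of all 5 groups (1.87). PDGFRA passed without unsorted tumor 4 (-1.18) (adjusted p = 0.0105 to 0.621 over its 29 alternatives). CRYAB and GLDN also lost their calls with limma-voom (3.34 and 4.03), and GLDN with 1 fit of all 5 groups (3.13). All unsorted tumor specimens had number codes and no gray or white matter specimen did, so kind of specimen and tissue cannot be told apart.

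The sixth comparison set unsorted tumor against white matter, with the same limit. The genes that passed both fell. C1orf95, named STUM in the annotation (chromosome 1, 226548800 to 226609214), stood at 0.510 ± 0.411 FPKM (SD, n = 8) against 6.12 ± 2.17 FPKM (SD, n = 3), a difference of -2.23 ± 0.26 (SE, adjusted p = 0.00355). KIF21B, a neuronal motor protein gene named after its values were seen, stood at 0.411 ± 0.277 against 3.71 ± 1.27 FPKM (-1.73 ± 0.20, adjusted p = 0.00355). C1orf95 passed under 25 of 26 alternatives (adjusted p = 0.00148 to 0.0934), but not with 1 fit of all 5 groups (-2.23). The phagocyte gene CYBB (2.21 ± 0.36, adjusted p = 0.0503) lay just short of the threshold. It passed without unsorted tumor 1, 6, 7 or 8 (2.08 to 2.33), with the GC trend taken off (2.14), limma-voom (2.50), no filter (2.21), a pseudocount of 0.1 (2.42), a pseudocount of 0.5 (2.32), quantile normalization (2.22), the specimen as a random effect (2.21), upper quartile scaling (2.16) and values rescaled to a common sum (2.39) and at a mean of 5 FPKM or more (2.21) (adjusted p = 0.0213 to 0.447 over its 28 alternatives). PECAM1, SOX2, OLIG2, PDGFRA, GFAP and PTPRC did not pass (adjusted p = 0.143, 0.427, 0.735, 0.539, 0.783 and 0.099). PECAM1 passed with an exact permutation test (1.14) (adjusted p = 0.0285 to 0.78 over its 29 alternatives), as did PTPRC (1.52) (adjusted p = 0.0164 to 0.792).

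In these lists, 0 members passed over all genes. Medians were positive for 21 microglia and macrophage markers (12 adjusted over the list alone, median 1.17, adjusted p = 1.3e-12, or 0.509 with an estimated correlation) and for 11 MHC class I and II genes (8 adjusted over the list alone, median 1.17, adjusted p = 7.1e-08, or 0.509 with an estimated correlation). They were positive for 21 mesenchymal-like glioma genes (12 adjusted over the list alone, median 1.48, adjusted p = 2.5e-08, or 0.509 with an estimated correlation) and for 21 cell cycle genes (1 adjusted over the list alone, median 1.02, adjusted p = 5.5e-07, or 0.509 with an estimated correlation). They were negative for 23 synapse genes (11 adjusted over the list alone, median -1.15, adjusted p = 4.3e-12, or 0.509 with an estimated correlation) and for 21 neuron markers (0 adjusted over the list alone, median -1.50, adjusted p = 9.4e-07, or 0.509 with an estimated correlation), the neuron median being -0.99 without white matter 14. Of the 31 lists tested, 13 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.509. The myelin list (median -0.68, adjusted p = 0.0926) passed without unsorted tumor 5, 6 or 7, or white matter 14 (-2.08 to -0.86) and with 1 fit of all 5 groups (-0.68) (adjusted p = 2.1e-06 to 0.908 over its 28 alternatives). The ribosomal list (median 0.16, adjusted p = 0.169) passed without white matter 13 or 14 (-0.35 to 0.76) and with the GC trend taken off (0.25) and limma-voom (0.47) (adjusted p = 4.5e-09 to 0.466 over its 28 alternatives), with a negative median without white matter 14.

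Limma called 0 genes higher and 2 lower of 11009, with 1798 at an unadjusted p under 0.05, and limma-voom 6 and 6. Leaving out unsorted tumor 1, 6, 7 or 8 gave 7 and 3, 3 and 4, 28 and 31, and 5 and 2, white matter 12 or 13 gave 1 and 2, and 0 and 4, and gray matter 13 gave 0 and 3.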

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

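No test in this part was chosen after the results were seen. In groups of 7 or 8 libraries, the gap between the highest or lowest library and its nearest neighbour was divided by the range of the group. This ratio passed Dixon's critical value in 31 of 231 groups of list means, gene levels and library measures, where chance flags about 1 in 20, and many of these genes share a list. No explanation was tested for these libraries, technical or biological.

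A2B5plus 6 lay apart in 11 values. It was highest in the pan-endothelial list (ratio 0.902, mean log2 level 3.18 against at most 0.58 in the others) and the blood-brain barrier list (0.740), and in ABCB1 (0.814), CD34 (0.807), CDH5 (0.842), CLDN5 (0.678), DLL4 (0.678), ERG (0.886), PECAM1 (0.603) and VWF (0.848). It was lowest in PDGFRA (0.597, 0.142 FPKM against 7.47 or more).

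A2B5plus 2 was highest in C3 (0.684), LYZ (0.817) and TLR2 (0.651) and lowest in the glial genes MAL (0.618), MOBP (0.569) and S100B (0.691). LYZ stood there at 78.1 FPKM against at most 1.41 in the others. A2B5plus 9 was highest in the T and NK cell list (0.684) and PLVAP (0.862), and A2B5plus 10 in the neuron list (0.650) and GABRB2 (0.704).

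Unsorted tumor 8 was lowest in the oligodendrocyte progenitor-like list (0.732) and OLIG2 (0.615), and highest in the hypoxia list (0.545), the erythrocyte list (0.574), CXCL8 (0.587), JUNB (0.550) and KLF4 (0.606). CXCL8 stood there at 27.2 FPKM against at most 3.28 in the others. Unsorted tumor 4 was highest in MFSD2A (0.589), PDGFRA (0.638, 43.7 FPKM against at most 9.96) and PPDPF (0.549).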

How the results depend on the processing

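Limma-voom, leaving out the 6 gene-poor libraries, and GC removal with or without the block were chosen after seeing the data, the rest before. Also after values were seen, the filter under rescaling and upper quartile scaling was set to that of the other fits, and the direction of a list, before that of camera, to the sign of its median. Of 448 gene counts under alternatives, 389 lay within 1.5 times the value reported, 33 were higher and 26 lower. Of 7010 values of single genes, 6813 kept their side of the threshold and, if called, direction, 136 lost and 61 gained a call. Of 7536 list values, 7258 kept both, 218 lost and 54 gained a call and 6 with a call changed sign. Sign changes with no call on either side are not counted. An estimated correlation ended 91 of the list calls, and fry 35, while fry added 4. Gains that the report leaves out were those of the fibroblast and mesenchymal-like lists in endothelial against A2B5plus, the synapse, hypoxia and basement membrane lists in A2B5plus against unsorted tumor, the ganglioside list in both comparisons with gray matter, and the stem cell and progenitor-like lists in unsorted tumor against white matter. Of the lists that passed, fry called 21 of 23, 27 of 27, 6 of 9, 0 of 5, 3 of 15 and 0 of 13 in the order of the report's comparisons. No gene count moved beyond 1.5 times with the block, the kind of code as a covariate, number-coded specimens alone, no trend or robust eBayes. The block changed the calls of the NOTCH, hypoxia, interferon and mesenchymal lists, each in 1 comparison, and no other. The cause was not tested, beyond the fewer genes or samples that some settings leave.

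In endothelial against A2B5plus, 1121 genes rose and 683 fell at a mean of 5 FPKM or more, where fewer genes were tested, 1797 rose and 2247 fell with array weights, and 1158 and 1758 without the gene-poor libraries. In endothelial against unsorted tumor, 1402 rose and 915 fell at that mean, and 6425 rose with array weights. In A2B5plus against unsorted tumor, 797 rose and 762 fell at that mean, 1607 and 3963 with upper quartile scaling, 1096 and 779 with the GC trend taken off, and 1061 and 672 with the block as well. There, 3307 fell with values rescaled to a common sum, 1304 with the 2 groups fitted alone and 712 without the gene-poor libraries. Gray against white matter gave 1 gene higher in gray matter with no filter. Unsorted tumor against gray matter gave 275 and 416 at the mean of 5 FPKM, and 107 and 725 in 1 fit of all 5 groups. Unsorted tumor against white matter gave 30 and 4 with a pseudocount of 0.1, 17 and 7 with 0.5, 2 and 13 with no filter, 2 and 0 at the mean of 5 FPKM, 23 and 20 with quantile normalization and 16 and 8 with upper quartile scaling. It gave 1 and 24 in 1 fit of all 5 groups, 6 and 6 with limma-voom and 6 and 4 with the GC trend taken off, and 25 rose with values rescaled and 4 with the specimen as a random effect.

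With 1 library left out, genes higher and lower ranged over 2452 to 3193 and 1633 to 2221 in endothelial against A2B5plus, 3801 to 4562 and 2585 to 3146 in endothelial against unsorted tumor, and 2084 to 2903 and 1651 to 2357 in A2B5plus against unsorted tumor. They ranged over 0 to 2 and 0 to 9 in gray against white matter, 55 to 639 and 184 to 1268 in unsorted tumor against gray matter, and 0 to 28 and 2 to 31 in unsorted tumor against white matter. With a call on either side, signs of medians changed for ribosomal genes of endothelial against A2B5plus with upper quartile scaling (0.13), of gray against white matter without white matter 13 (0.18, range over libraries left out -0.91 to 0.18) and of unsorted tumor against white matter without white matter 14 (-0.35, range -0.35 to 0.76). In A2B5plus against unsorted tumor they changed for the pan-endothelial list without the gene-poor libraries (-0.45) and with block and GC removal (-0.46), and for the arterial list with these (-0.43).

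Array weights were not used in unsorted tissue, where they did not converge, a choice made after seeing 1 weight of 115. Depth and spread limit the gene tests: 4% to 24% of simulated 2-fold and 64% to 88% of 16-fold changes were recovered, and genes with 1 FPKM or more in fewer than 3 libraries of a fit were not tested. Kind of specimen code and tissue are confounded in tumor against gray or white matter.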

Other observations

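The tests of leukocytes, of free RNA, of white matter 14 and of other splits were chosen after their results were seen, and those of code kind, length, GC content and abundant genes before.

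Macrophage transcripts were abundant in the endothelial libraries, with SPP1 at 506 ± 373, LAPTM5 at 344 ± 200 and FCER1G at 195 ± 141 FPKM (SD, n = 11), against 90.4 ± 65.2, 56.2 ± 34.9 and 15.7 ± 12.7 FPKM in unsorted tumor (SD, n = 8). The kind of specimen code is argued against as the whole cause by the list's median difference within number-coded specimens (3.07). Free RNA of the dissociated tumor, if of the same make-up as unsorted tumor, would bring at most its levels. The median lay 2.57 above these, with 24 of 25 genes higher. The make-up of free RNA was not measured, so free RNA richer in macrophage transcripts stays open. A candidate source is leukocytes among the sorted cells: over the endothelial libraries the macrophage list fell as the pan-endothelial list rose (r = -0.741). Of its 25 genes, 21 reached 1 FPKM in unsorted tumor and 8 in gray matter, and 0 were in another list. A gate that excludes PTPRC would remove such cells, but the markers are not given, and the macrophage relation did not pass within number-coded libraries (r = -0.544).

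Of the 4 other relations with the pan-endothelial list over the 11 endothelial libraries, that of the pericyte list was positive (r = 0.843, rho = 0.809, permutation p = 0.00164 and 0.00383, adjusted p = 0.0082). Without the 2 farthest libraries and within number-coded ones its r passed (0.728 and 0.864, exact permutation p = 0.0250 and 0.00637) and its rho did not (0.667 and 0.714, p = 0.0589 and 0.0576). That of the T and NK cell list was negative (r = -0.735, rho = -0.564, permutation p = 0.0121 and 0.0752, adjusted p = 0.0202). In the same subsets its r was -0.653 and -0.712 (p = 0.0571 and 0.0487) and its rho -0.350 and -0.476 (p = 0.359 and 0.243), so only 1 of these 4 passed. The neutrophil and immediate early lists did not pass (r = -0.339 and -0.168, adjusted p = 0.382 and 0.626), though the neutrophil rho without the 2 farthest libraries was -0.700 (p = 0.0433).

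Ribosomal protein and immediate early genes were higher in sorted than in unsorted tumor libraries, by medians of 1.72 and 3.85 for endothelial cells. Random lists of like length and level had medians of 0.39 to 1.20 and -0.44 to 0.63 (the middle 95%), those of like GC content 0.42 to 1.29 and 0.72 to 1.94, and those of both 0.66 to 1.46 and 0.38 to 1.75. The share of random lists below was 100% and 100% for length, 99.99% and 100% for GC content, and 99.95% and 100% for both, so these argue against length and GC content as the whole cause. With each library rescaled without its 100 highest genes the ribosomal median was 1.8, which argues against a few abundant genes. A response to dissociation and sorting, the amount of RNA put into a library and a difference in cell types all go with the group and stay open.

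White matter 14 resembled gray matter, with MBP at 31.9 FPKM against 1992 and 6414 in white matter 12 and 13. A single library under both labels is argued against, as the reads of both libraries of specimen 14 differed by a chi-square per degree of freedom of 6.31, which covers counting error alone and was the lowest of 496 pairs, the next being 12.23, so that 2 libraries made from 1 RNA stay open. Swapped labels are argued against by the myelin mean of gray matter 14, 1.55, where the other white matter libraries had 5.70 and 6.25. Over 1014 genes outside the myelin, neuron and synapse lists that differed in specimen 12, the median gray minus white difference, signed that way, was -0.0596 in specimen 14 and 1.46 in specimen 13. Gray matter tissue in the piece labelled white is a candidate explanation, and a single wrong label or 2 libraries of 1 piece would give such values.

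Other splits of the samples tested whether chance can be excluded for the numbers of genes called. It can for endothelial against A2B5plus (4578 genes, highest other split 2656), endothelial against unsorted tumor (7160, 4147), A2B5plus against unsorted tumor (4460, 699) and unsorted tumor against gray matter (1607, 1032), where 1 of 100 splits, the real one, gave as many. Few of these splits part all pairs of libraries of 1 specimen (7, 8 and 5 in the first 3 comparisons), but of 100 that do, again 1, the real one, gave as many, with 3053, 3577 and 2486 genes in the highest other, which left 6 of 7, 0 of 8 and 5 of 5 pairs in place. Chance cannot be excluded for unsorted tumor against white matter, where 13 of 100 splits gave as many as the real 2. The highest gave 523, and what set that split apart was not tested. For gray against white matter the 10 splits are too few for a share under 0.05, with 0 genes in the real split and 2 in the highest other.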
